A study of Mus musculus with 4 samples.

How the data were processed

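RNA-seq of MEL cells was analysed for 4 samples in 2 groups, uninduced and DMSO-induced (1.5% DMSO), with replicates 1 and 2 in each, as the sample titles give them. Per the labels' protocols, RNA was extracted with Trizol and ribosomal RNA was depleted with Ribo-Zero before fragmentation and library preparation. Per the submitters' processing notes, TopHat2 and GRCm38 were used; versions, the quantifier, the annotation release, strandedness and read depth were not given in the sources used here. The deposited table held 1 FPKM column per sample, with no pooling. The unit was inferred: per the file headers its columns are those of a Cufflinks tracking table, the values were not whole and summed to more than CPM or TPM allow in every sample, and low values in single-exon genes of 380 to 520 bp clustered at a constant divided by length. That constant gave the relative depths, provided that values were scaled to each library's total alone. It could not give whole counts for each locus, so no count was recovered and no count model such as edgeR or DESeq2 was used. The design fixed in advance named a count test first and the FPKM test used here for the case that no counts were given. By definition FPKM is relative to the total of each library, so a few very abundant transcripts lower the value of the others. The alternatives on scaling address this. Since the quantifier is unknown, other scaling factors may have been applied, which was not tested.

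Loci were identified by the table's own identifiers and symbols. Transcripts were matched to GENCODE M21 (43405 of 47935 loci), which supplied gene types, transcript length and GC content. Loci with 1 symbol counted as that gene; a list member whose locus was shared by several genes was left out of the list tests, a rule set after the table was seen. Starts in the table counted from 0 and were raised by 1; the table's positions span whole clusters of overlapping transcripts, so gene positions were taken from GENCODE. Loci outside the table were not analysed here. An exact 0 may be a failed estimate. There were 68 loci listed at 0 in 1 sample and at 5 FPKM or more in the other 3, including the housekeeping gene Clpp. Most of the 68 were short loci without a symbol, and most had their 0 in an induced sample. Clpp had its 0 in uninduced replicate 2.

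The test used log2(FPKM + 1) for the 12890 loci with at least 1 FPKM in at least 2 samples, fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend and without robust estimation) with group as the only term, and Benjamini-Hochberg adjustment over all loci at 0.05. SEs are limma's moderated ones. Gene lists were fixed before the data were examined, 28 in all, and 24 had at least 5 members tested. They were tested with camera at a preset inter-gene correlation of 0.01, two-sided, adjusted over the 24 lists; 12 passed. With an estimated correlation none passed by camera (0 at an unadjusted p of 0.05 as well), while fry, a self-contained test of whether members move one way on balance, passed 9. Shares of the table were compared with an exact two-sided permutation test over 6 arrangements.

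Named genes were chosen by a rule fixed before the data were examined. It took the 8 risen and 8 fallen genes with the largest log2 change among those past the threshold, with separated replicates, a mean of at least 5 FPKM, and neither a provisional symbol nor a pseudogene. To these it added the most abundant and the most changed called member of each list, and a fixed set of erythroid and progenitor genes. Results of some genes that the rule took or that completed a small count are not reported here. Other genes were named after their values were seen, to complete small counts.

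The fit was tested on simulated data for the 12890 loci of the comparison of DMSO-induced with uninduced samples, in 20 simulations each. With 200 loci changed, limma recovered 5.6% of 2-fold, 70% of 4-fold and 98.3% of 16-fold changes, and 10.7% of the calls were false. With 3400 loci changed, a number set near the observed one, it recovered 57.3%, 95.2% and 99.8%, with 3.67% of calls false. These used each locus's moderated spread. A first version with unmoderated spreads shuffled between loci, 200 loci changed and folds of 1.5, 2 and 4 recovered 0% at each fold; the simulation was then revised and the fit left as it was, so the higher recoveries depend on the spreads assumed. Lists of 20 members planted at 2-fold passed camera at an unadjusted p under 0.05 in 20 of 20 simulations and unplanted lists in 0. The simulated loci varied independently, while the estimated inter-gene correlations of the fixed lists ran up to 0.866. The simulation therefore cannot show how camera with the preset correlation treats correlated lists.

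Alternatives fixed in advance were 3 other scalings (quantile, median-of-ratios, and sums without globins and the 10 most abundant loci), no filter, a filter at 5 FPKM, a pseudocount of 0.1, a replicate block, leaving out each sample, a minimum change of 1.2-fold, and other denominators for shares. Restriction to protein-coding loci, removal of loci listed at 0, a fit with no trend, lists with shared loci and further denominators, including one without Rn7sk, were added after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and figures.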

Results

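MEL cells are a mouse erythroleukemia line that is blocked at an early erythroid stage and resumes erythroid-like differentiation when dimethyl sulfoxide (DMSO) is added to the medium. Ribosomal RNA-depleted total RNA was sequenced from 2 uninduced and 2 DMSO-induced samples, the latter grown with 1.5% DMSO. The length of exposure was not given in the sources used here. The comparison asked which transcripts differed between the uninduced and the induced state. Expression was given as FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of each library) for 47935 loci, of which 42707 carried 1 gene symbol, 1103 several and 4125 none. FPKM summed to 1055861 and 1325806 in uninduced replicates 1 and 2, and to 1246536 and 1100517 in induced replicates 1 and 2. Between 12151 and 12645 loci per sample reached 1 FPKM. Sequencing depth was not given. It was estimated from the step of the lowest values in short single-exon genes, assuming scaling to each library's total alone. Relative to uninduced 2, uninduced 1, induced 1 and induced 2 stood at 0.92, 0.71 and 0.74. All positions below are on GRCm38, from the GENCODE M21 annotation unless another source is named.

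DMSO-induced cells had a different transcriptome from uninduced cells, with a rise of most globin, heme synthesis and red cell membrane transcripts and a fall of most ribosome biogenesis transcripts among the fixed gene lists. Of 12890 loci tested, 3377 passed a Benjamini-Hochberg adjusted p of 0.05 in limma-trend, 1478 higher and 1899 lower after induction. At least 2-fold changes were seen for 2631 of them, 1106 higher and 1525 lower. The balance turned under quantile normalization, with 1819 higher and 1692 lower, and 1314 higher and 1308 lower at least 2-fold. Among 9840 loci of protein-coding genes, 1094 were higher and 1331 lower. Replicates correlated at 0.959 (uninduced) and 0.956 (induced) across loci, against 0.841 to 0.881 between groups; loci are not independent replicates. Both induced values lay on 1 side of both uninduced values for 70.8% of the loci, where chance gives 33.3%. The number of calls rested on both replicates of each group and on the filter. It was 30 without uninduced replicate 1 and 14 without uninduced replicate 2, all of them lower, 486 without induced replicate 1, 67 without induced replicate 2, and 30 when low loci were kept, and between 26 and 54 of the 54 genes past the threshold that the naming rule took no longer passed when 1 sample was left out. Bax, Cdk4, Gata2, Mcm5, Pmvk, Trib3, Cd9 and Ifi35 also fell short of the threshold under at least 1 of the 3 other scalings (limma adjusted p from 0.0512 to 0.151). The labels did not say whether replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes, and are given ± SE; FPKM values are mean ± SD over n = 2 samples per group.

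Globin transcripts had the highest median change of the fixed lists. Hbb-bs, an adult beta-globin gene (chromosome 7, 103826534 to 103828096), went from 113 ± 24.7 to 27783 ± 16947 FPKM, a log2 fold change of 7.80 ± 0.51 (limma adjusted p = 0.00601). Hba-a1, an adult alpha-globin gene (chromosome 11, 32283511 to 32284465), went from 786 ± 185 to 53995 ± 19367 FPKM (6.07 ± 0.45, adjusted p = 0.00721). Its neighbour Hba-a2 (chromosome 11, 32296489 to 32297298) went from 9.56 ± 2.52 to 579 ± 306 FPKM, and Hbb-bt (chromosome 7, 103812524 to 103813996), the other adult beta-globin gene, from 8.19 ± 5.56 to 174 ± 85.4 FPKM. The split between Hba-a1 and Hba-a2 and between Hbb-bs and Hbb-bt is uncertain, since reads from these near-identical copies can be assigned to either. Of 8 globin genes tested, 7 rose and none fell, also 7 when adjusted over the list alone, with a median log2 fold change of 4.30. The 1 not called was the embryonic gene Hbb-bh1 (log2 fold change 0.67, adjusted p = 0.214), named after its values were seen. The list was shifted upward relative to other loci (camera adjusted p = 4.9e-06 with a preset correlation; adjusted p = 0.587 with an estimated correlation).

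Globin genes took 0.0734% and 0.0822% of the summed FPKM in the uninduced samples and 4.56% and 9.89% in the induced samples. Their mean share was 0.0778% ± 0.00622 against 7.23% ± 3.77 (SD, n = 2 each), a difference of 7.15 percentage points (two-sided exact permutation p = 0.333, the smallest that 2 against 2 samples allow). With protein-coding nuclear loci as the total the difference was 11.7 points. The RNA Rn7sk, at 233708 FPKM in induced replicate 1 and listed at 0 in induced replicate 2, weighs on these totals; without it the difference was 7.66 points. The 10 most abundant loci of each sample, not 1 fixed set, took 27.3% and 34.9% of the uninduced and 38.7% and 27.8% of the induced tables. The difference of 2.16 points lay within the spread between replicates (exact permutation p = 0.667). That difference was 3.1 points without Rn7sk, 6.04 points over protein-coding nuclear loci and 7.13 points over protein-coding loci with 1 symbol. The last 2 count a locus in the span of Filip1l, at 63155 FPKM in uninduced replicate 2 and 4627 to 5597 in the other samples.

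Genes of heme synthesis had 9 of 12 members that rose. Alas2, the erythroid enzyme of the first step of the pathway (chromosome X, 150547375 to 150570638), went from 53 ± 15.3 to 2415 ± 1308 FPKM (log2 fold change 5.40 ± 0.45, adjusted p = 0.00906). Of 12 list members tested, 9 rose, none fell and 3 did not pass, with a median log2 fold change of 1.64; adjusted over the list alone, 10 rose and 1 fell. The upward shift had a camera adjusted p of 9.39e-05, and an adjusted p = 0.593 with an estimated correlation. Iron genes moved both ways. Of 20 tested, 3 rose, 4 fell and 13 did not pass, 9 were called when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.667). Tfrc, the transferrin receptor (chromosome 16, 32608920 to 32632794), rose from 100 ± 83.3 to 506 ± 51.1 FPKM (2.62 ± 0.64, adjusted p = 0.0405), with uninduced values of 159 and 41.0. The other risen members were the mitochondrial iron importer Slc25a37 and the ferritin autophagy receptor Ncoa4, and the fallen ones included Hmox1 (heme oxygenase), Pcbp1 and Slc48a1; these 5 were named after their values were seen.

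Red cell membrane and skeleton genes rose in 17 of 26 members tested and fell in 1, with 8 not past the threshold and a median log2 fold change of 1.56 (camera adjusted p = 1.94e-07; adjusted p = 0.587 with an estimated correlation). Adjusted over the list alone, 20 rose and 1 fell. Slc4a1, the band 3 anion exchanger (chromosome 11, 102348824 to 102366203), went from 0.52 ± 0.05 to 135 ± 73.2 FPKM (6.36 ± 0.41, adjusted p = 0.0059). The 1 that fell was the adhesion receptor Cd44, whose level drops in erythroid maturation (25.4 to 4.28 FPKM on average), named after its values were seen. Of 27 erythroid maturation genes and enzymes tested, 12 rose and 1 fell (median 0.92, camera adjusted p = 9.39e-05; adjusted p = 0.587 with an estimated correlation). Adjusted over the list alone, 17 rose and 1 fell. Prdx2, an abundant red cell peroxidase (chromosome 8, 84969587 to 84974834), rose from 644 ± 105 to 1963 ± 399 FPKM (1.60 ± 0.29). Car1, carbonic anhydrase 1 (chromosome 3, 14766216 to 14808368), had the largest fall of all named genes on the log2(FPKM + 1) scale. It went from 486 ± 89.8 to 12.4 ± 8.15 FPKM (-5.32 ± 0.47, limma adjusted p = 0.01). By the ratio of mean FPKM (0.0254 for Car1), Hdc (0.0153), Hemt1, Tyrobp, Gml and Thy1 (0.00402) fell further.

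**Figure D1:**
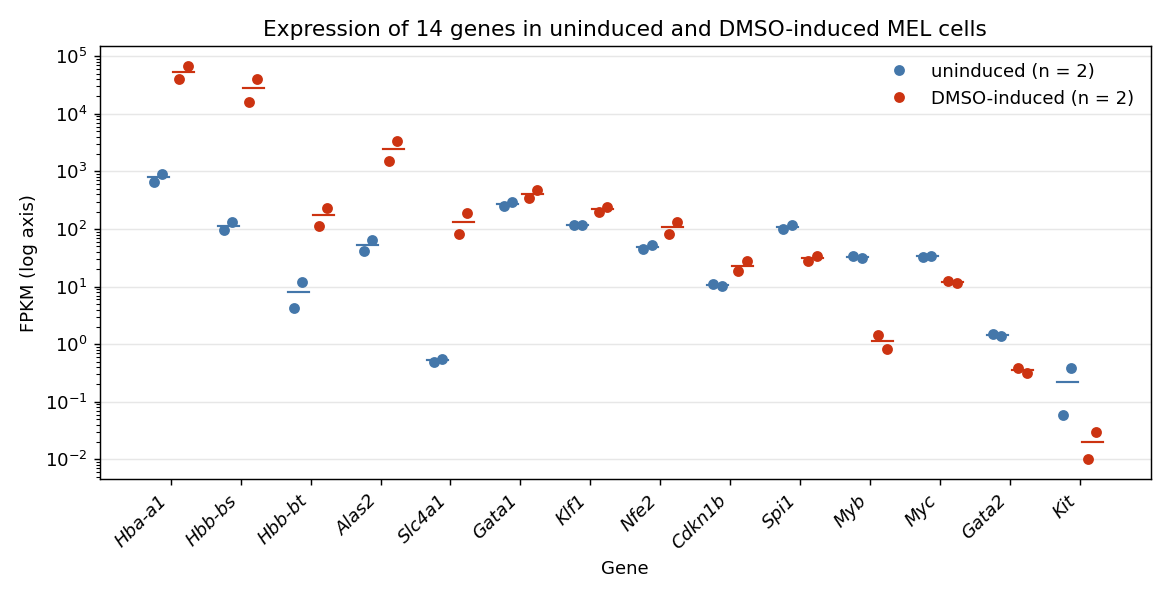
FPKM on a log axis of 14 erythroid, progenitor and cell cycle genes fixed for reporting, with 1 point per sample (blue, uninduced; red, DMSO-induced) and a bar at each mean of n = 2. Hba-a1, Hbb-bs, Alas2 and Slc4a1 stand far above their uninduced values, Myb, Spi1 and Myc lie below theirs, and Kit stays under 1 FPKM in all samples.

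Erythroid transcription factors went in both directions. Of 25 tested, 5 rose, 4 fell and 16 did not pass, and the list did not pass (median 0.48, camera adjusted p = 0.456); adjusted over the list alone, 9 rose and 8 fell. Foxo3 (chromosome 10, 42181841 to 42276755) rose from 21.5 ± 2.33 to 111 ± 24.9 FPKM (2.30 ± 0.24, adjusted p = 0.0115). Klf1 (chromosome 8, 84901928 to 84905291), an activator of adult beta-globin, rose from 117 ± 0.57 to 221 ± 30.2 FPKM (0.91 ± 0.20, adjusted p = 0.0336). Gata1, the central erythroid factor (chromosome X, 7959260 to 7978071), measured 268 ± 30.4 and 410 ± 89.3 FPKM (0.60 ± 0.25, adjusted p = 0.138). Nfe2 (chromosome 15, 103248212 to 103258403) measured 49.7 ± 5.57 and 107 ± 34.3 FPKM (1.05 ± 0.28, adjusted p = 0.05, on the far side of the threshold). Neither passed. Nfe2 did under quantile scaling (limma adjusted p = 0.0297) and scaling without globins and the 10 most abundant loci (0.0411). It also passed with the 5 FPKM filter (0.0482), protein-coding loci only (0.0159) and removal of loci listed at 0 (0.0435). It did not pass under median-of-ratios scaling or with a pseudocount of 0.1. Tal1, Klf3 and Sox6 also rose, and Lmo2, Bcl11a, Stat5a and Ikzf1 fell, named after their values were seen.

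Progenitor and leukemia regulators had 7 of 17 members that fell. Myb, a proto-oncogene of immature blood cells (chromosome 10, 21124935 to 21160984), went from 33 ± 2.11 to 1.15 ± 0.45 FPKM (-4.00 ± 0.24, adjusted p = 0.00459). Spi1, which encodes PU.1 and is activated by retroviral insertion in many MEL lines (chromosome 2, 91082390 to 91115756), went from 108 ± 9.75 to 30.8 ± 3.92 FPKM (-1.78 ± 0.20, adjusted p = 0.0128). Myc (chromosome 15, 61985391 to 61990374) went from 33.8 ± 1.14 to 12.1 ± 0.81 FPKM (-1.41 ± 0.19). Gata2 (chromosome 6, 88193891 to 88207032) fell from 1.44 ± 0.11 to 0.36 ± 0.05 FPKM. Kit, the stem cell factor receptor (chromosome 5, 75574916 to 75656722), was at 0.06 and 0.38 FPKM in uninduced and 0.01 and 0.03 in induced samples, too low to be tested. Of 17 members tested, 7 fell, 1 rose (Runx1, named after its values were seen) and 9 did not pass, with the same counts when adjusted over the list alone. The median was -0.63 (camera adjusted p = 0.00979; adjusted p = 0.587 with an estimated correlation).

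DNA replication genes fell in 10 of 36 and rose in none, also 10 when adjusted over the list alone. The median was -0.68 (camera adjusted p = 9.39e-05, or 0.727 with an estimated correlation, and 0.206 by fry, a self-contained test). Few were higher in replicate 2 than in replicate 1: 4 of 36 in the uninduced samples (median log2 difference -0.24) and 2 of 36 in the induced ones (-0.43). Mcm2, a subunit of the replicative helicase (chromosome 6, 88883474 to 88898780), went from 98 ± 5.29 to 36.8 ± 5.93 FPKM (-1.40 ± 0.21), and Mcm5 (chromosome 8, 75109569 to 75128439) from 157 ± 31.7 to 69.7 ± 17.6 FPKM. Of 18 replication-dependent histone genes, 2 fell (Hist1h2ae, and Hist1h2ag, the latter named after its values were seen), also 2 when adjusted over the list alone. Hist1h2ae (chromosome 13, 23570517 to 23571220) went from 559 ± 153 to 177 ± 57.8 FPKM. Histone genes have near-identical copies, so their single values are uncertain. The list's median was -0.86 (camera adjusted p = 0.0064; adjusted p = 0.798 with an estimated correlation, and 0.352 by fry), and the list did not pass without uninduced replicate 2 (adjusted p = 0.175). All 18 were higher in uninduced replicate 2 than in uninduced replicate 1 (median log2 difference 0.74). The mitosis list did not pass: 3 of 31 rose (Cdc25b, Nusap1 and Cdc25c, the last 2 named after their values were seen), 2 when adjusted over the list alone, and none fell (median 0.30, camera adjusted p = 0.128). Whether that list passed depended on the sample left out. It passed without uninduced replicate 1 or induced replicate 2, but not without uninduced replicate 2 or induced replicate 1. Whether the replication and mitosis lists differed was not tested. Cdc25b, a phosphatase that activates mitotic kinases (chromosome 2, 131186949 to 131198497), rose from 8.61 ± 0.09 to 43.8 ± 10.3 FPKM.

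Among cell cycle arrest and G1 regulators, 9 of 24 rose and 2 fell (median 0.79, camera adjusted p = 0.00273; adjusted p = 0.593 with an estimated correlation, and 0.055 by fry). Adjusted over the list alone, 13 rose and 2 fell. Btg2, an antiproliferative gene (chromosome 1, 134075170 to 134079120), rose from 24.4 ± 5.50 to 263 ± 87.1 FPKM (3.35 ± 0.31, adjusted p = 0.0106). Cdkn1b, the cyclin-dependent kinase inhibitor p27 (chromosome 6, 134920401 to 134925513), rose from 10.7 ± 0.69 to 23.2 ± 6.64 FPKM (1.02 ± 0.26, adjusted p = 0.0447). The 2 that fell were Cdk4 (chromosome 10, 127063534 to 127067920), from 254 ± 0.51 to 126 ± 17.3 FPKM, and Cdkn1a, the latter named after its values were seen. Autophagy and mitophagy genes rose in 8 of 23 and fell in none, 9 rising when adjusted over the list alone (median 0.64, camera adjusted p = 0.00286; adjusted p = 0.689 with an estimated correlation, and 0.148 by fry). Gabarap (chromosome 11, 69991143 to 69994951) rose from 100 ± 0.59 to 298 ± 119 FPKM and Map1lc3a (chromosome 2, 155276297 to 155278073) from 6.46 ± 3.13 to 34.8 ± 11.5 FPKM; both encode proteins of the autophagosome membrane.

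Ribosome biogenesis genes fell almost as a block. Of 29 tested, 27 fell, none rose and 2 did not pass (Npm1 and Polr1c, named after their values were seen), and all 29 fell when adjusted over the list alone. The median was -1.72 (camera adjusted p = 5.29e-13; adjusted p = 0.593 with an estimated correlation). Rrp9, a component of the small-subunit processome (chromosome 9, 106475963 to 106485424), went from 115 ± 3.25 to 16.2 ± 3.84 FPKM (-2.78 ± 0.23, adjusted p = 0.00871), and Nhp2, a pseudouridylation cofactor (chromosome 11, 51619735 to 51623714), from 295 ± 19.2 to 113 ± 19.3 FPKM (-1.39 ± 0.22). Ribosomal protein genes gave a different picture: none of 21 was called by limma, 0 also when adjusted over the list alone and 0 at an unadjusted p under 0.05. Their median was -0.02, with a sign that changed with the scaling (-0.10 to 0.04), and their mean 0.01 (camera adjusted p = 0.901, upward). Which of the 2 lists moved more was not tested as a difference.

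The list for the integrated stress and unfolded protein response was lower after induction, with 11 of 20 fallen, 1 risen and 8 not past the threshold (median -1.57, camera adjusted p = 0.00172; adjusted p = 0.593 with an estimated correlation, and 0.0883 by fry). Adjusted over the list alone, 12 fell and 1 rose. Phgdh and Trib3 are known targets of ATF4, a transcription factor of this response. Phgdh, the first enzyme of serine synthesis (chromosome 3, 98313170 to 98339990), went from 595 ± 131 to 71 ± 28.5 FPKM (-3.09 ± 0.35, adjusted p = 0.0128). Trib3 (chromosome 2, 152337422 to 152344032) fell from 136 ± 149 to 6.57 ± 0.59 FPKM (-3.54 ± 0.94, adjusted p = 0.0493), with uninduced values of 30.7 and 242 that stood far apart. Of the list's 20 members, 16 were higher in uninduced replicate 2 than in uninduced replicate 1 (median log2 difference 0.76). The member that rose was Eif2ak1, the heme-regulated eIF2alpha kinase, named after its values were seen.

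The remaining fixed lists of cell functions did not pass camera. Interferon response genes had 4 risen and 2 fallen of 11 (camera adjusted p = 0.214, but 0.0277 by fry, upward). The risen were Irf7, Ifi35, Stat2 and Ddx58, and the fallen Isg15 and Bst2, those other than Irf7 and Ifi35 named after their values were seen. Irf7 (chromosome 7, 141262706 to 141266481) went from 1.60 ± 0.53 to 11.5 ± 0.97 FPKM and Ifi35 (chromosome 11, 101448407 to 101458698) from 22.9 ± 4.09 to 40.4 ± 2.47 FPKM. Glycolysis genes had 2 fallen and none risen of 19 (camera adjusted p = 0.203, but 0.0381 by fry, downward). Hk2, hexokinase 2 (chromosome 6, 82725025 to 82774454), went from 30.1 ± 13.5 to 6.90 ± 1.07 FPKM, and Eno3 was the other, named after its values were seen. Cholesterol genes had 2 fallen and none risen of 22 (camera adjusted p = 0.226, but 0.0206 without uninduced replicate 2). Pmvk, phosphomevalonate kinase (chromosome 3, 89454541 to 89469013), was among the fallen and went from 139 ± 3.19 to 85.3 ± 4.36 FPKM. Adjusted over each list alone, 4 rose and 2 fell among interferon genes, 2 fell in glycolysis and 1 fell in the cholesterol list.

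Apoptosis regulators had 2 risen and 1 fallen of 20 (camera adjusted p = 0.0662). Bcl2l11, which encodes the pro-apoptotic BIM (chromosome 2, 128126038 to 128162547), rose from 2.46 ± 1.27 to 8.93 ± 2.29 FPKM, Birc2 rose as well (named after its values were seen), and Bax (chromosome 7, 45461697 to 45466898) fell from 106 ± 9.61 to 62.8 ± 3.69 FPKM. Chromatin regulators had 4 risen and 1 fallen of 25 (camera adjusted p = 0.687). Ezh1 (chromosome 11, 101191115 to 101226463) rose from 2.94 ± 0.68 to 10.2 ± 2.97 FPKM and Hdac6 (chromosome X, 7930120 to 7947889) from 7.38 ± 0.28 to 15.5 ± 2.25 FPKM; Kat2b and Ep300 rose and Dnmt3b fell, named after their values were seen. None of 16 CTCF, cohesin and condensin genes was called by limma, 0 also when adjusted over the list alone and 4 at an unadjusted p under 0.05. As a list their median was 0.44 (camera adjusted p = 0.0634). The list passed with loci shared with other genes counted (camera adjusted p = 0.0331). It also passed without uninduced replicate 1 or induced replicate 2, but not without uninduced replicate 2 or induced replicate 1. In each group 1 of the 16 genes was higher in replicate 2 than in replicate 1. Replacement histones had 3 risen and 3 fallen of 9 (camera adjusted p = 0.893), with a median of -0.09 whose sign changed with the scaling and a mean of 0.11. H1f0, the linker histone of non-dividing cells (chromosome 15, 79028450 to 79030504), rose from 91.1 ± 45.3 to 539 ± 112 FPKM (2.63 ± 0.40), and H3f3a (chromosome 1, 180800832 to 180813943) from 446 ± 17.2 to 879 ± 9.65 FPKM. H2afv also rose, and H2afy, H2afj and Hist1h1t fell, named after their values were seen. Adjusted over each list alone, 1 apoptosis gene rose, 3 chromatin genes rose, and 3 replacement histones rose and 4 fell. The mitochondrially encoded transcripts lay in loci shared by several genes and were not tested as a list.

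**Figure D2:**
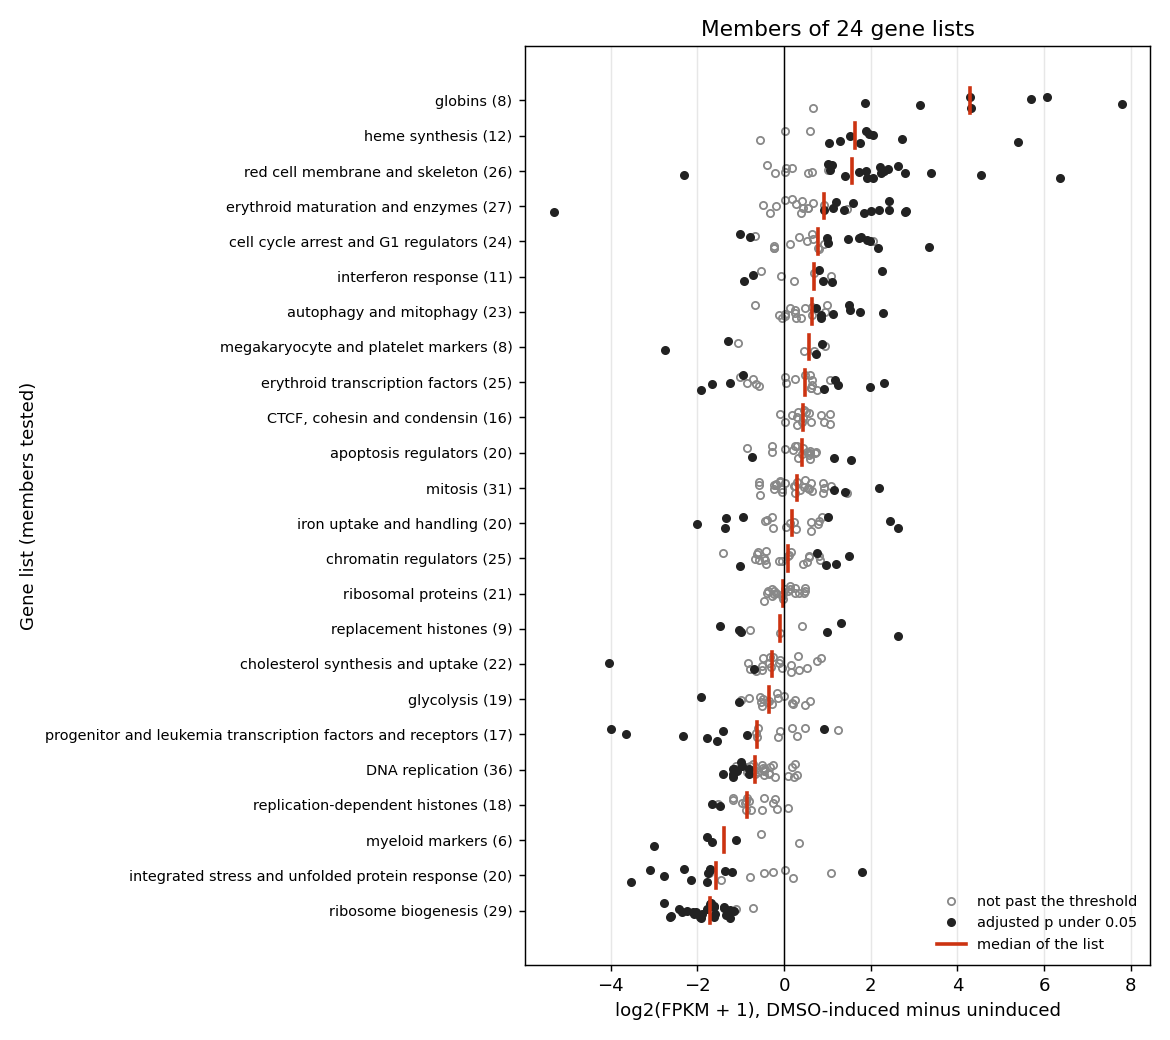
Each point is 1 member of 1 of the 24 gene lists with at least 5 members tested, placed by its log2(FPKM + 1) difference of DMSO-induced minus uninduced samples (n = 2 each; vertical scatter carries no value). Filled points passed the limma threshold, open points did not, and the red bar is the list's median, from 4.30 for globins to -1.72 for ribosome biogenesis.

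Markers of other blood lineages were mostly low or fell. Tested were 6 of 23 myeloid, 8 of 20 megakaryocyte, 4 of 13 mast cell, 2 of 19 lymphoid and 2 of 14 fibroblast or endothelial markers. Untested markers with a locus of their own stayed under 1 FPKM. Fcgr3, Hdc and Thy1 passed the filter only through their uninduced samples, so they could not have been seen to rise. The myeloid list test rests on the 6 that passed the filter. Of 6 myeloid markers tested, 4 fell and none rose, the same 4 when adjusted over the list alone (median -1.39, camera adjusted p = 0.0187; adjusted p = 0.587 with an estimated correlation). Cebpa (chromosome 7, 35119293 to 35121928) went from 16.4 ± 2.03 to 7.09 ± 0.88 FPKM and the Fc receptor gene Fcgr3 (chromosome 1, 171051174 to 171064935) from 9.40 ± 1.73 to 0.30 ± 0.18 FPKM; Ncf1 and Cd68 fell too, named after their values were seen. Megakaryocyte markers had 2 risen and 2 fallen of 8, with 4 rising and 3 falling when adjusted over the list alone. Gp5 (chromosome 16, 30307685 to 30310779) fell from 19.3 ± 1.92 to 2.03 ± 0.63 FPKM and Cd9 (chromosome 6, 125460266 to 125494791) rose from 27.4 ± 2 to 46.4 ± 5.04 FPKM; Treml1 fell and Vwf rose, named after their values were seen. That list's median was 0.57 and its mean -0.18 (camera adjusted p = 0.725, upward). Mast cell markers had 2 fallen of 4 tested (Hdc and, named after its values were seen, Il1rl1). Hdc, histidine decarboxylase (chromosome 2, 126593667 to 126619299), went from 38.3 ± 17.6 to 0.58 ± 0.02 FPKM (-4.56 ± 0.36). Both lymphoid markers tested fell: Thy1 (chromosome 9, 44043384 to 44048579) went from 14.9 ± 1.41 to 0.06 ± 0.04 FPKM, and Cd79b was named after its values were seen. Of 2 fibroblast or endothelial markers, Vim (vimentin, chromosome 2, 13573927 to 13582826) fell from 164 ± 61.9 to 12.4 ± 0.18 FPKM, and Tek (1.37 and 0.47 FPKM on average, adjusted p = 0.0563) did not pass. Over each list alone, 2 mast cell, 2 lymphoid and 2 fibroblast or endothelial markers fell; these 3 lists were too short for a set test.

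Several of the largest changes lay outside the fixed lists. Apol11b, of the apolipoprotein L family (chromosome 15, 77633946 to 77643286), rose from 0.25 ± 0.03 to 74 ± 23.1 FPKM (5.87 ± 0.28, adjusted p = 0.00293). Cgn, which encodes the tight junction protein cingulin (chromosome 3, 94760069 to 94786492), rose from 2.35 ± 0.54 to 119 ± 71.7 FPKM (5.03 ± 0.46), and Cox6b2, a cytochrome c oxidase subunit known from testis (chromosome 7, 4751792 to 4753094), from 2.57 ± 2.38 to 96.8 ± 63.4 FPKM (4.78 ± 0.67). Hemt1 (chromosome 15, 74819071 to 74841643 in the deposited table) fell from 54.5 ± 0.24 to 0.55 ± 0.23 FPKM (-5.17 ± 0.22, adjusted p = 0.00258). Its neighbour Gml (chromosome 15, 74813452 to 74818815) measured 35.5 and 30.4 FPKM in uninduced samples and 0.47 in induced replicate 1, and was listed at 0 in induced replicate 2 (-4.80 ± 0.27, adjusted p = 0.00395). Tyrobp, a signalling adaptor of myeloid cells (chromosome 7, 30413760 to 30417585), measured 19 and 21.4 FPKM in uninduced samples, 0.36 in induced replicate 1 and was listed at 0 in induced replicate 2 (-4.18 ± 0.25). Phlda2 (chromosome 7, 143501545 to 143503150), an imprinted gene, fell from 112 ± 18 to 5.16 ± 0.62 FPKM (-4.19 ± 0.22).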

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

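Protein-coding loci only, removal of loci listed at 0, no trend, lists with shared loci and shares without Rn7sk were chosen after the data were seen. The 3377 calls ranged from 2635 to 4238, and the 2631 of at least 2-fold from 1798 to 2964, over the other scalings, the 5 FPKM filter, the pseudocount of 0.1, the replicate block and the added settings. With no filter both fell to 30 of 26323 loci (6813 at an unadjusted p under 0.05); the cause was not tested. Leaving out 1 sample gave 14 to 486 calls for both (3406 to 4940 unadjusted), in fits with 1 sample fewer where the lone sample is assumed to vary like the other group. Against a minimum change of 1.2-fold 2162 loci passed, as a stricter null requires. The share of calls that were higher went from 43.8% to between 39.4% and 51.8% over scalings, turning the balance under quantile normalization, and the median of all loci moved by less than 0.1. The count-based DESeq2 alternative was not run, since no counts were used.

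With the replicate block 4238 loci were called, 2964 at least 2-fold. By camera 14 lists passed, mitosis (adjusted p = 0.0332) and CTCF, cohesin and condensin (0.00803) in addition to the 12. Among the genes that the naming rule took, Nfe2 then passed (limma adjusted p = 0.0284) and Pmvk did not (0.0521). The replicate differences correlated at 0.17 between groups (0.271 over loci above 0 in every sample); with 2 pairs and no label on what a number marks, this does not show a pairing, nor exclude a shared day. Some lists differed alike between the replicates in both groups. Of CTCF, cohesin and condensin genes, 1 of 16 was higher in replicate 2 in each group. So were, in the uninduced and induced samples, 5 and 1 of 31 mitosis genes and 4 and 2 of 36 DNA replication genes. For ribosome biogenesis the counts were 6 and 1 of 29, and for cholesterol genes 3 and 2 of 22. Ribosomal protein genes went the other way, with 19 and 21 of 21 higher in replicate 2 (median log2 differences 0.16 and 0.32). Of the 12 lists past the threshold, 0 passed with an estimated correlation (camera adjusted p from 0.587 to 0.977 over all lists). The estimates ran from -0.0162 to 0.866. They were -0.00305 for the progenitor list and 0.0117 for myeloid markers, against the preset 0.01. These values argue against a higher correlation as what ended the calls of those lists. For the other lists, whether the estimates or the few residual degrees of freedom ended the calls was not tested. By fry 9 lists passed, of which 7 were among the 12 and the others were interferon response and glycolysis, and 12 to 14 passed when 1 sample was left out. The direction turned only for lists not past the threshold: megakaryocyte markers by fry (adjusted p = 0.8) and without uninduced replicate 1 (0.95; 0.622 to 0.95 over samples left out), ribosomal proteins without uninduced replicate 1 (0.715) and without induced replicate 2 (0.53; 0.41 to 0.715), cholesterol without uninduced replicate 1 (0.95; 0.0206 to 0.95), replacement histones without uninduced replicate 2 (0.927; 0.836 to 0.945) and chromatin regulators without induced replicate 1 (0.974; 0.347 to 0.997); the cause was not tested. None of the 56 tested genes that the naming rule took turned direction under the settings run; genes named after their values were seen were not followed through them. The globin share difference of 7.15 points was 7.17 to 11.7 with other denominators and that of the 10 most abundant loci 2.19 to 7.13; the exact test of 2 against 2 cannot pass, so its p says nothing of stability. Depth, about 0.71 to 1 of the deepest sample, limits low loci most.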

Other observations

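The gene groups below were picked after the values of 30 symbol families had been looked at, and no enrichment was tested for them. Of the tests of explanations, those on the most abundant short loci and on the scaling of ribosome biogenesis were chosen only after the result was seen. Counts are of loci. Bootstrap SEs below come from resampling loci, which share the same libraries, so they do not measure variation between samples or cultures. Aminoacyl-tRNA synthetase loci fell in 12 of 18 and rose in 1, a minor Cars locus (1.18 to 4.1 FPKM, while the abundant Cars locus measured 37.9 and 15.3 FPKM, limma adjusted p = 0.0517), with a median log2 fold change of -1.31; Gars measured 225 and 344 FPKM in the uninduced and 80.2 and 61.8 in the induced samples, and 15 of the 18 loci were higher in uninduced replicate 2 than in uninduced replicate 1 (median log2 difference 0.34). A group of serine and one-carbon genes, assembled partly from genes seen to fall, had 12 of 14 fallen. Psph, the last enzyme of serine synthesis, measured 55.3 and 109 FPKM in the uninduced and 10.7 and 5.57 in the induced samples (-3.16 ± 0.44). In the uninduced samples 6 of the 14 were higher in replicate 2 than in replicate 1, and in the induced ones 0 of 14 (median log2 difference -0.70). Mitochondrial ribosomal protein genes fell in 33 of 72 and rose in none (median -0.76), RNA polymerase subunits fell in 10 of 27, proteasome genes in 9 of 43 with 1 risen (Psme4), chaperonin subunits in 4 of 6 (Cct2, Cct3, Cct5 and Cct7) and nucleoporins in 4 of 16 (Nup37, Nup43, Nup85 and Nup210). Complex I subunits and assembly factors had 2 risen (Ndufa1 and Ndufa3) and 3 fallen (Ndufs8, Ndufaf5 and Ndufaf6) of 43, with a median of -0.02 whose sign changed with the scaling. V-type ATPase subunits rose in 3 of 16 (Atp6v0a1, Atp6v1d and Atp6v1e1).

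All 4 apolipoprotein L genes tested rose, all on chromosome 15. In each, only the induced samples reached the filter of 1 FPKM, so a fall could not have been seen. Genes of the family low in both groups were not tested. Apol11b and Apol8 had low but measured uninduced values (0.25 and 0.46 FPKM), Apol10a measured 0.01 on average, and Apol11a was listed at 0 in both uninduced samples and at 6.61 and 11.1 FPKM in the induced ones. The nuclear RNA Malat1 (chromosome 19, 5795690 to 5802672, GRCm38) rose from 77.6 ± 10.6 to 439 ± 160 FPKM (2.44 ± 0.31, limma adjusted p = 0.0141). Ribosomal RNA of the locus Rn18s-rs5 stood at 15598 FPKM in uninduced replicate 2 against 41.4 to 129 in the other samples, and a locus in the span of Filip1l at 63155 against 4627 to 5597. Rn7sk was listed at 0 in induced replicate 2 and at 93378 to 233708 FPKM elsewhere.

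Ribosome biogenesis transcripts fell with induction while the ribosomal protein list did not pass. A GC content or transcript length trend between the groups is argued against as the whole cause, since the list's median was -1.75 (bootstrap SE 0.11) after the trend was removed, against -1.72 before. Under the 3 other scalings the list's median stayed between -1.80 and -1.66 (bootstrap SE 0.13 at the latter). Those scalings put the median of all loci between -0.04 and 0.09, against 0.03 before. They had little room to move the list, so this test cannot decide on scaling as a cause. A scaling difference moves all loci alike, while the list stood at -1.72 and all loci at 0.03. The list thus fell relative to the other loci. All these values are relative and cannot show a change in total RNA per cell. That the fall belongs to the induced state is a hypothesis; DMSO itself and differentiation cannot be separated in this design, and it was found and tested on the same data.

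Among protein-coding loci with 1 symbol, those that rose stood mostly higher in induced replicate 2 than in induced replicate 1 (74.3%; Tfrc, at 469 against 542 FPKM, went the other way), and those that fell mostly lower (27% higher), with median log2 differences of 0.18 (bootstrap SE 0.01, 1016 loci) and -0.16 (SE 0.01, 1250 loci). In induced replicate 2, 6 of 8 globin, 9 of 12 heme synthesis and 19 of 26 red cell membrane genes were higher, but so were 6 of 8, 9 of 12 and 14 of 26 in uninduced replicate 2. A different scaling of the induced libraries would move both sets the same way, which the -0.16 argues against. A GC content or length trend is argued against too, since the difference of risen minus fallen loci was 0.33 before and 0.44 (SE 0.02) after the trend was removed. Between the uninduced replicates, the medians of replicate 2 minus 1 were -0.08 for risen, -0.05 for fallen and -0.15 for uncalled loci. As sets, risen and fallen loci thus did not part there. Of DNA replication genes, 4 and 2 of 36 were higher in uninduced and induced replicate 2. Of ribosome biogenesis genes, 6 and 1 of 29 were. The values go with induced replicate 2 lying further along the same change. Whether through a higher share of responding cells or a later stage was not tested. For globin, heme synthesis, DNA replication and ribosome biogenesis genes, a difference shared by the samples numbered 2 stays open.

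Loci without a symbol followed the span of their listed positions. The median log2 fold change was -1.24 below 200 bp (306 loci), -0.85 from 200 to below 400 bp (684) and -0.36 from 400 to below 1000 bp. It was 0.26 from 1000 to below 5000 bp and 0.35 from 5000 bp. Listed positions cover whole clusters of overlapping transcripts, and separate loci of Filip1l carry the same span. A short locus within a cluster is thus counted as long, and the bins are not of transcript length. Fragment size or length bias may contribute and cannot be told apart. Annotated loci under 400 bp differed from those of 5000 bp or more by -0.02, but with a bootstrap SE of 0.22 over only 62 short loci. That comparison used the same listed spans. Few fragments per locus stays open too, since the 171 most abundant of the 684 loci of 200 to below 400 bp had a median of -0.23 (SE 0.16). A link to the gene around them could not be tested, as 0 of 990 short loci lay inside 1 tested locus with 1 symbol. Listing by cluster can give this 0 by itself, so it says nothing about where these loci lie. Of the 68 loci described above with a 0 in 1 sample, most were short, without a symbol and at 0 in an induced sample. Their weight in these medians was not tested. No biological explanation was tested.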
